A study of Arabidopsis thaliana with 66 samples.

How the data were processed

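The study measured RNA from Arabidopsis thaliana flowers, floral organs, pedicels and pollen on ATH1 arrays, with 66 arrays in 22 groups of 3. The deposited values are signal intensity on a linear scale, made by the authors with MAS5, whose version is not given. The trimmed mean of each array lay between 99.91 and 99.97, so the authors' table is scaled to a common level per array, and the arrays were used with that scaling. Signals ran from 0.00753 to 20033. No pair of arrays held identical values. Precision is limited by the 3 arrays per group.

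The floor was the 40th percentile of all values, 22.61, and the pseudocount 0.5 of it, 11.31. Of 22810 probe sets, 64 controls were left out and 5100 were removed as dim, because in no group did all arrays lie above the floor. The remaining 17646 were tested. Of the probe sets other than controls, 13513 pair with 1 gene, 503 with several and 8730 with none in the annotation used. Only those with 1 gene are named, and they are 9810 of those tested, for 9704 genes. No member of the planned floral homeotic list has such a probe set, so these genes are not analysed here.

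Log2(signal + 11.31) was fitted with limma 3.58.1 in R 4.3.3 with 1 mean per group over all 66 arrays, followed by contrasts and eBayes with a trend (44 residual degrees of freedom, prior 10.6). A probe set was called at a Benjamini-Hochberg adjusted p below 0.05, within the comparison, and a change of at least 2-fold. An organ's enriched probe sets passed this against each other organ of the stage. A group whose arrays all lie at or below the floor is called below the floor, and a fold against it is the other group's mean over the floor, given as "at least". Comparisons, groups, the naming rule and the alternatives were set before the data were examined.

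Gene lists were tested with limma's camera (preset correlation 0.01, two-sided), adjusted over 576 tests of lists with at least 3 tested members and, for the 4 organ lists in 7 mutants, over 28. The lists planned beforehand held few genes with a named probe set. A further 18 lists were therefore built from the gene names in the annotation after this was seen but before values of single genes were looked at, and the lists whose tests the text gives are of this kind, except mature pollen and pollen tube and tapetum and pollen wall. Single genes are also named from other planned lists. Over all list tests 183 passed, and 142 of these also passed with an estimated correlation.

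Genes named in the text follow a rule: mutated genes and members of the homeotic and meristem lists. Per comparison it adds the 6 largest increases and the 6 largest decreases whose replicates do not overlap, or the 8 largest smallest differences for an organ. Per comparison and list it adds up to 4 called members with the largest change. A gene with several probe sets is given by the one with the highest mean. The text names fewer than the rule allows. The level of AtVEX1 in ap1-15, which is outside the rule, was added after its values were seen.

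The procedure was tested on simulated data with the same 24 comparisons. Of the genes changed 3-fold, 99% to 100% were recovered, and of those changed 8-fold 100%, with 0 false calls. A first version drew only bright genes, and the draw was then widened to all genes above the floor. Shifted lists passed in 24 of 24 comparisons and unshifted lists in 0. The simulated noise was independent between probe sets and these p-values were not adjusted. The simulation therefore does not show how often lists with correlated members pass without a change.

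Alternatives tried were no pseudocount, a pseudocount equal to the floor, no filter on dim probe sets, quantile normalization, each array divided by its 75th percentile, only the arrays of the groups compared, eBayes with robust=TRUE, the replicate letter as a block, each array left out in turn, and camera with an estimated correlation. Regroupings of the same arrays were counted for each comparison. The levels of long-day flowers were left out of the tests, because photoperiod, temperature and an unstated stage differ together.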

Results

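Gene expression was measured in flowers, dissected floral organs, pedicels (the flower stalks) and mature pollen of Arabidopsis thaliana on 66 one-colour ATH1 arrays, in 22 groups of 3 arrays. Wild-type Col-0 plants gave whole flowers at stages 9, 10/11, 12 and 15, sepals, petals, stamens and carpels at stages 12 and 15, pedicels at stage 15, and mature pollen. A further wild-type group holds flowers of unstated stage from plants grown in long days at 20 °C, whereas the plants of the other flower and organ groups grew in continuous light at 23 °C. The remaining 7 groups are flowers, taken at the equivalent of stage 12, of plants mutated in genes of the floral meristem or of floral organ identity: clv3-7, lfy-12, ap1-15, ap2-6, ap3-6, ag-12 and ufo-1. Each array carried 22810 probe sets. The number of probe sets above the floor, a signal of 22.61, averaged 14359 ± 156 (SD, n = 3) in stage 12 flowers and was lowest in mature pollen, at 11936 ± 184, or 52.5% ± 0.808 of the probe sets. The 100 brightest probe sets held 22.9% ± 0.600 of the pollen signal and 7.82% to 11.3% of the mean signal of every other group. Replicate arrays correlated at 0.9864 or more across probe sets, except in pollen, where the lowest correlation was 0.9636. Throughout, ± gives the SD over the 3 arrays of a group, fold changes are on the log2(signal + 11.31) scale, which understates the change of dim genes, and p-values describe the spread between these plant samples only, pooled over the 22 groups.

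Each mutant was compared with wild-type flowers of stage 12 to ask which transcripts depend on the mutated gene and on the organs it specifies. The mutated genes themselves could not serve as a check of the labels. Of the 7, only UFO and CLV3 have a probe set that pairs with a single named gene, and both lay below the floor in all mutant and stage 12 arrays. The number of probe sets called (at least 2-fold, adjusted p below 0.05) was lowest in clv3-7, at 123, of which 75 were higher and 48 lower than in the wild type. Without a pseudocount it was 193, with 91 higher and 102 lower, so that balance depends on the processing. In lfy-12 flowers 1729 were called, 432 higher and 1297 lower. The counts were 984 in ap1-15 (364 higher, 620 lower), 1134 in ap2-6 (257 and 877), 1290 in ap3-6 (195 and 1095), 1249 in ag-12 (186 and 1063) and 897 in ufo-1 (149 and 748). All were out of 17646 probe sets tested. For each gene list and comparison, the counts of called members adjusted over the list alone were the same as over all genes tested (672 combinations). Of the list tests below, 64 passed with the preset correlation and 8 of these, all of the chloroplast-encoded list, did not with an estimated correlation.

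**Figure D1:**
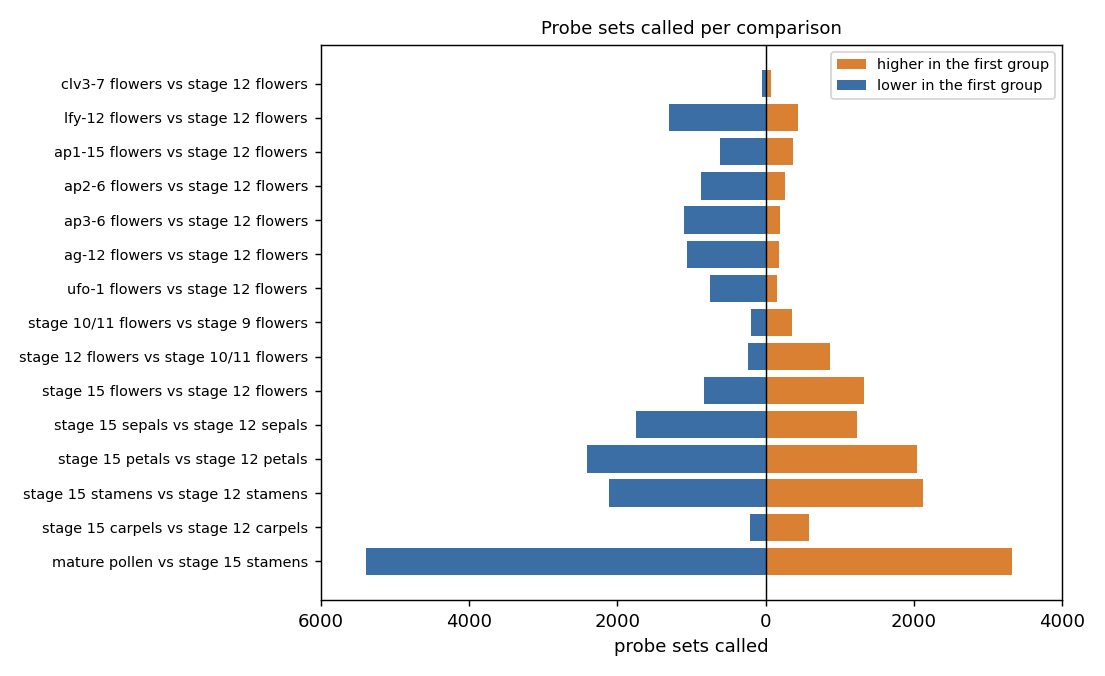
Number of probe sets called higher (right, orange) or lower (left, blue) in each comparison of 2 groups, out of 17646 tested, with 3 arrays per group. The count ran from 123 in clv3-7 flowers to 8705 between pollen and stage 15 stamens.

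To relate these calls to organs, 4 lists were made from the dissected wild-type organs of stage 12: the probe sets at least 2-fold higher in an organ than in each of the other 3 (1199 for sepals, 294 for petals, 1691 for stamens and 894 for carpels). In the other mutants than clv3-7 the stamen list fell furthest. Its median log2 change was -1.01 in lfy-12, -1.003 in ag-12, -0.98 in ap3-6 and -0.76 in ufo-1, with 857, 848, 838 and 654 members called lower. It was -0.57 in ap2-6, -0.43 in ap1-15 and 0.07 in clv3-7, where 14 members were called higher and 0 lower. The petal list fell in lfy-12 (-0.30), ap1-15 (-0.37), ap2-6 (-0.43), ap3-6 (-0.35) and ufo-1 (-0.36) but rose in ag-12, where its median was 0.40, with 24 members called higher and 1 lower (adjusted p = 5.46e-15). Carpel genes were higher as a list in ap2-6 (0.57), lfy-12 (0.55), ap3-6 (0.52), ap1-15 (0.35) and ufo-1 (0.34). In lfy-12 the carpel list split, with 135 members called higher and 78 lower. In ag-12 its median was 0.02 while the test, which was not passed, pointed to lower (adjusted p = 0.0993), and 91 members were called lower and 4 higher. That test passed with a pseudocount equal to the floor (adjusted p = 0.009), quantile normalization (0.0267) and division by the 75th percentile (0.0339). The sepal list was higher in ufo-1 (0.19, 89 members called higher) and ag-12 (0.13), lower in ap2-6 (-0.34) and ap1-15 (-0.14), and did not pass in lfy-12 (0.02, with the test pointing to lower) or ap3-6 (0.02). In clv3-7 the shifts were small: the sepal list (-0.08, adjusted p = 2.19e-05) and the petal list (-0.07, adjusted p = 0.00453, not passed without a pseudocount) passed as lower, the stamen list as higher (adjusted p = 0.00342), and the carpel list did not pass (adjusted p = 0.159). List tests used limma's camera with a preset correlation of 0.01, adjusted over 28 tests, and with an estimated correlation all 28 lists kept their side of the threshold. Differences between mutants in these 4 lists were tested separately, in 84 tests.

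**Figure D2:**
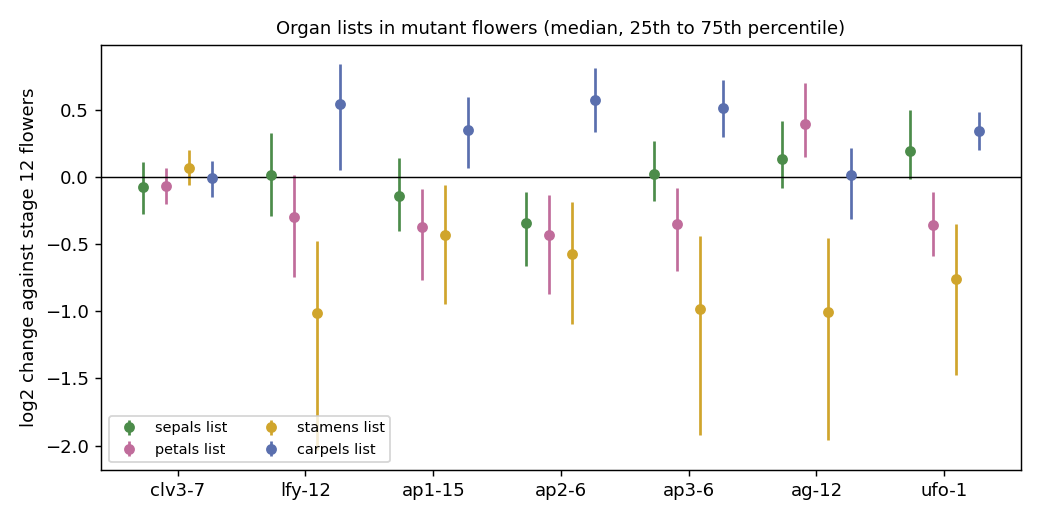
Log2 change against wild-type stage 12 flowers of 4 organ lists in 7 mutants. Points are the medians of each list's probe sets and bars span the 25th to the 75th percentile of its members. The petal list lies above 0 in ag-12 (median 0.40) and below 0 in the other mutants.

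The 6 largest increases among named genes in clv3-7 were of the 6 genes with the largest decreases from stage 10/11 to stage 12 in the wild type. Both comparisons use the same stage 12 arrays, with opposite sign, which by itself draws them toward the same genes, and no value for the overlap without a shared change was computed. LCR66 (AT1G61070), a low-molecular-weight cysteine-rich protein gene, reached 196 ± 6.71 against a level below the floor, at least 8.68-fold higher (log2 fold change 3.69, SE 0.15, adjusted p = 1.28e-27). AT5G07230, a member of the planned tapetum and pollen wall list, reached 94.6 ± 4.46 against a level below the floor, at least 4.18-fold higher, and SHT (AT2G19070) of the same list 208 ± 10.2 against 34.9 ± 2.37. Of the 4 tested members of that list 2 were called higher (median 1.44, adjusted p = 4.92e-09). This list was also higher in ap1-15 (2.57) and ap2-6 (1.54) and lower in ag-12 (-1.57). In ap1-15 flowers LCR66 was at 950.2 ± 67.8 against a level below the floor, at least 42-fold higher (log2 fold change 5.90, SE 0.15, adjusted p = 3.85e-38), with AT1G02813 at 703 ± 25.3 against a level below the floor, at least 31.1-fold higher and SHT at 449 ± 12.8 against 34.9 ± 2.37. The transcription factor gene AMS (AT2G16910) was 171 ± 11.2 against 39.9 ± 1.19 (log2 fold change 1.83, SE 0.20, adjusted p = 3.11e-11), a call lost without a pseudocount (adjusted p = 0.076). In ap2-6 flowers AT5G07230 stood at 359.9 ± 20.4 against a level below the floor, at least 15.9-fold higher (log2 fold change 4.85, SE 0.12, adjusted p = 7.09e-38) and LCR66 at 204 ± 20.9 against a level below the floor, at least 8.99-fold higher. LCR66 also lay above the floor in lfy-12 (124.1 to 149.5 per array) and ufo-1 (38.65 to 49.35). The anther and tapetum list (10 genes tested) was higher in clv3-7 (median 0.40, adjusted p = 1.7e-09), ap1-15 (0.86, adjusted p = 2.63e-06) and ap2-6 (0.55, adjusted p = 0.000785, and 0.0559 without a pseudocount). It was lower in ap3-6 (-0.82, adjusted p = 0.000615) and ag-12 (-1.499, adjusted p = 1.23e-06).

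Genes of later male development were lower in 6 mutants. The list of pollen and male gamete genes had 16 of 25 members lower in lfy-12, 12 in ap1-15, 15 in ap2-6, 16 in ap3-6, 15 in ag-12 and 14 in ufo-1, with no member called higher in these 6 and medians from -1.69 in ap3-6 to -0.92 in ap1-15. In clv3-7 no member was called (median 0.10, adjusted p = 0.354). PLIM2a (AT2G45800), at 164 ± 15.3 in the wild type, was below the floor in lfy-12, ap1-15, ap3-6, ag-12 and ufo-1, at least 7.23-fold lower, and at 19.5 ± 4.6 in ap2-6. AtVEX1 (AT5G62850) fell from 457 ± 24.4 in the wild type to 45 ± 1.97 in ufo-1 and 142 ± 5.39 in ap2-6 and lay below the floor in lfy-12, ap3-6 and ag-12. In ap1-15 it was at 259 ± 25.1, less than 2-fold lower and not called. In lfy-12, ap3-6 and ag-12 the largest decreases were of genes at over 1000 in wild-type flowers. AT3G28790 was below the floor against 1742 ± 67.2, at least 77-fold lower (log2 fold change -6.96, SE 0.12, adjusted p = 3.93e-48) in ag-12, and AT1G66850 was below the floor against 3340 ± 277, at least 147-fold lower (log2 fold change -7.67, SE 0.18, adjusted p = 2.5e-41) in ap3-6.

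**Figure D3:**
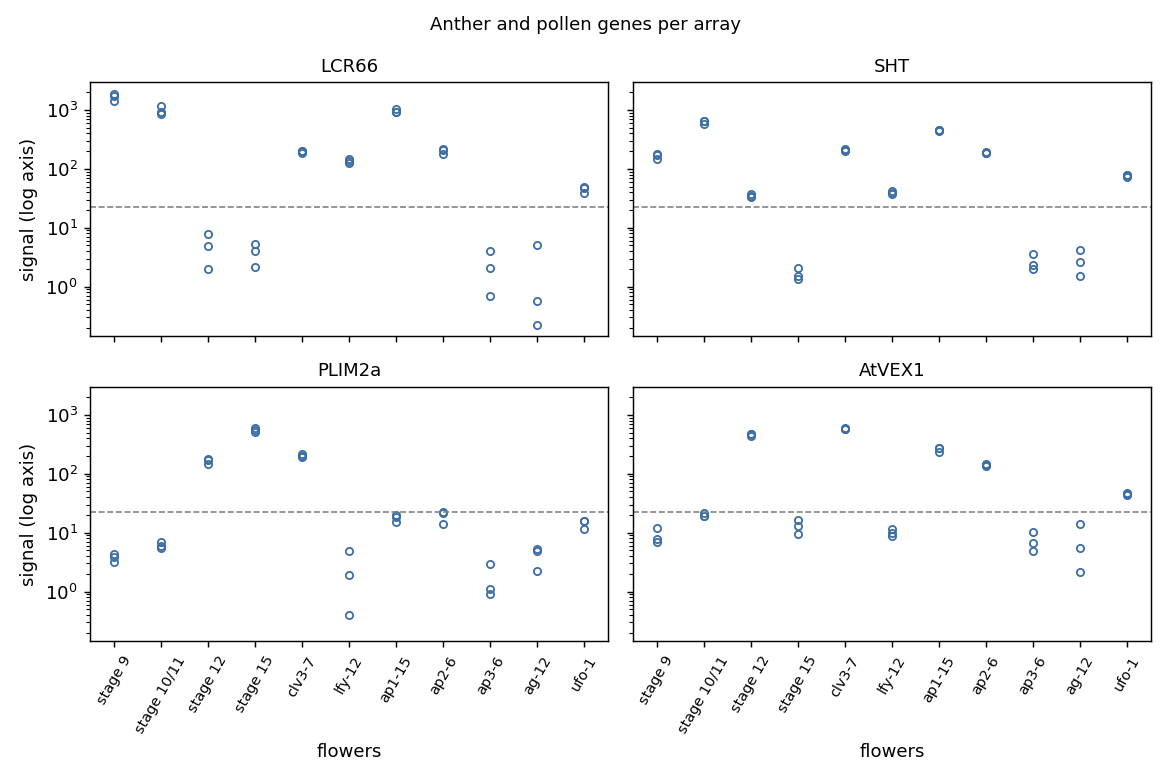
Signal per array (log10 axis) of LCR66, of SHT from the tapetum and pollen wall list, and of 2 pollen genes, PLIM2a and AtVEX1, in wild-type flowers of 4 stages and in the flowers of 7 mutants, with the floor as a dashed line. LCR66 has its highest mean in stage 9 flowers (1687) and reaches 950.2 in ap1-15.

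In lfy-12, AGL24 (AT4G24540) of the floral and shoot meristem list was 53.2 ± 11.6 against a level below the floor, at least 2.32-fold higher (log2 fold change 2.02, SE 0.20, adjusted p = 1.24e-12). It was the 1 member of that list tested. ROXY1 (AT3G02000) was 38.4 ± 6.35 against a level below the floor, at least 1.68-fold higher. In ag-12 and ufo-1 the chitinase gene CHI (AT2G43570) was among the largest increases, at 266 ± 36.4 against 36.2 ± 1.81 (log2 fold change 2.53, SE 0.16, adjusted p = 1.3e-20) and 211 ± 12.3 against 36.2 ± 1.81 (log2 fold change 2.22, SE 0.16, adjusted p = 6.14e-18), as was AT1G76960, at 77.7 ± 4.36 and 53.7 ± 3.6. The same 2 genes were the most sepal-enriched at stage 15. In ap3-6 the glucosinolate-modifying gene AOP3 (AT4G03050) was 185 ± 11.2 against a level below the floor, at least 8.15-fold higher (log2 fold change 3.53, SE 0.22, adjusted p = 1.6e-20). The methyltransferase genes BSMT1 (AT3G11480) and JMT (AT1G19640) fell in ap3-6, BSMT1 from 259.5 ± 14.6 to a level below the floor and JMT to 42 ± 2.62 against 158 ± 10.8. CES (AT1G25330) of the ovule, style and female gametophyte list, at 191 ± 4.28 in the wild type, was below the floor in ag-12 and lfy-12, at least 8.44-fold lower. In ap2-6, the carpel gene SPT (AT4G36930) was 154 ± 5.39 against 54.8 ± 5.09 (log2 fold change 1.32, SE 0.11, adjusted p = 4.31e-16). The cell division machinery list was higher in lfy-12 (median 0.70, adjusted p = 5.12e-05), ap2-6 (0.68, adjusted p = 6.51e-06), ap3-6 (0.44, adjusted p = 0.00488) and ap1-15 (0.42, adjusted p = 0.00852), with TOPII (AT3G23890) at 402 ± 15.2 against 146 ± 27.8 in lfy-12. Of 69 chloroplast-encoded genes, 22 were higher in lfy-12, 19 in ufo-1, 17 in ag-12, 13 in ap1-15, 10 in ap2-6 and 10 in ap3-6. As a list this passed the test with the preset correlation in each of the 6 but not with an estimated correlation (adjusted p from 0.143 to 0.371). The same held in clv3-7, with 4 genes higher (median 0.17, adjusted p = 0.000112, and 0.426 with an estimated correlation).

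The organ comparisons ask which genes mark an organ at stages 12 and 15. A gene counted as enriched in a floral organ when it was called against each other floral organ of that stage. Pedicels were not among these, and their own enriched genes were called against each floral organ of stage 15. The counts of list members, and a list's median and test, compare the organ with the mean of the other organs. Beside each enriched gene stands its level in the organ that came nearest. In stage 12 sepals, UGT76B1 (AT3G11340) was 360.3 ± 45.4 against a level below the floor in stamens, at least 15.8-fold and AT5G43450 644 ± 26.4 against a level below the floor in petals, at least 28.4-fold. The nuclear photosynthesis list was higher in sepals, with 25 of 30 genes higher than that mean (median 1.75, adjusted p = 1.06e-17). Early wound and touch genes were also higher than the mean of the other organs, 7 of 10 at stage 12 and 6 at stage 15, with CML41 (AT3G50770) at 331 ± 32.7 against 27.9 ± 2.56 in carpels. Stage 15 sepals were marked by CHI, at 1478 ± 91.3 against 29.2 ± 1.02 in petals, by the transcription factor gene WRKY53 (AT4G23810), at 234 ± 9.2 against 34.1 ± 4.07 in carpels, and 4 of 7 senescence-associated genes were higher than the mean of the other organs (median 1.92, adjusted p = 0.00251). Petals had the fewest enriched probe sets at both stages, 294 at stage 12 and 227 at stage 15, against 1691 and 863 for stamens, 894 and 2558 for carpels and 1199 and 920 for sepals. AT4G24140 led at stage 12, with 1074 ± 56.3 against 44.5 ± 3.99 in sepals, and CYP71B27 (AT1G13070) at stage 15, with 472 ± 17.6 against 20.8 ± 3.95 in stamens.

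In stage 12 stamens all 9 tested members of the mature pollen and pollen tube list were higher than the mean of the other organs (median 4.24, adjusted p = 1.8e-08) and again at stage 15 (median 2.81). MGH3 (AT1G19890) was 568 ± 34.3 against a level below the floor in petals, at least 25.1-fold. The dehydration gene LEA (AT2G21490) was 1192 ± 89.6 against a level below the floor in sepals, at least 52.6-fold, and 6 of 11 genes of its list were higher than the mean of the other organs (adjusted p = 0.00249). ATA27 (AT1G75940) was 812 ± 15.5 against a level below the floor in sepals, at least 35.9-fold. At stage 15 the sugar exporter gene SWEET14 (AT4G25010) was the most stamen-enriched named gene, at 1902 ± 188 against 22 ± 2.52 in sepals, with PLIM2a at 2793 ± 150 against 136 ± 8.89 in carpels. In carpels the cell division machinery list had 16 of 20 members higher than the mean of the other organs at stage 12 (median 1.28, adjusted p = 1.98e-06) and 14 at stage 15. CES was 758 ± 52.2 against a level below the floor in sepals, at least 33.5-fold and INO (AT1G23420) 168 ± 2.98 against a level below the floor in petals, at least 7.4-fold. The terpene synthase gene AT5G44630 was 1022 ± 6.5 against 38 ± 7.33 in sepals. Stage 15 carpels held the most enriched probe sets of any organ, 2558. GILT (AT4G12960) was 3432 ± 228 against a level below the floor in stamens, at least 152-fold, BAN (AT1G61720) 265 ± 10.4 against a level below the floor in petals, at least 11.7-fold and STOMAGEN (AT4G12970) 119.8 ± 12.2 against a level below the floor in stamens, at least 5.28-fold. Pedicels at stage 15 had 442 enriched probe sets, led by PRA1.F1 (AT1G17700) at 199 ± 4.79 against a level below the floor in petals, at least 8.8-fold, and 25 of 30 nuclear photosynthesis genes were higher than the mean of the 4 floral organs (median 1.81, adjusted p = 1.7e-13).

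Whole flowers were compared step by step to follow development. From stage 9 to 10/11, 354 probe sets rose and 201 fell. ATA27 rose from 421 ± 14.1 to 2247 ± 43.6 (log2 fold change 2.38) and SHT from 164 ± 16.5 to 626 ± 35.2, while AMS fell from 747 ± 77.2 to 197 ± 23.5 (adjusted p = 2.63e-11, and 0.148 without a pseudocount) and ROXY2 (AT5G14070) fell from 46.1 ± 9.34 to a level below the floor. From stage 10/11 to 12, 865 rose and 242 fell. The arrays of stages 9 and 10/11 are labelled A2, B2 and C2 and those of stage 12 A, B and C. A difference between these label series cannot be told apart from stage at this step. The largest decreases among named genes were of those with the largest increases in clv3-7, with AT5G07230 below the floor against 866 ± 33.1, at least 38.3-fold lower (log2 fold change -6.09, SE 0.12, adjusted p = 1.56e-43) and LCR66 below the floor against 983 ± 158, at least 43.1-fold lower (log2 fold change -5.94, SE 0.15, adjusted p = 4.54e-39). The anther and tapetum list fell (median -0.94, adjusted p = 3.38e-07) as 16 of 25 pollen and male gamete genes rose (adjusted p = 1.32e-18), AtVEX1 to 457 ± 24.4 against a level below the floor, at least 20.2-fold higher and PLIM2a to 164 ± 15.3 against a level below the floor, at least 7.23-fold higher. GILT had the largest increase, to 1288 ± 62.6 against a level below the floor, at least 56.9-fold higher (log2 fold change 5.92, SE 0.24, adjusted p = 5.57e-29). The chloroplast-encoded list also fell at this step, with 26 of 69 genes lower (adjusted p = 8.95e-17, and 0.0741 with an estimated correlation). From stage 12 to 15, 1331 rose and 828 fell. CYP71B31 (AT3G53300) was 857 ± 80.1 against a level below the floor, at least 37.8-fold higher (log2 fold change 6.11, SE 0.14, adjusted p = 5.91e-41), the sugar exporter gene SWEET9 (AT2G39060) 838 ± 37.8 against 26.4 ± 2.76 (log2 fold change 4.49, SE 0.17, adjusted p = 5.16e-30), and the terpene synthase gene AT3G25810 312 ± 9.94 against 29.5 ± 7.93. ATA27 was below the floor against 929 ± 35, at least 41.1-fold lower. Senescence-associated genes were higher at stage 15, 5 of 7 (median 2.37, adjusted p = 1.25e-06), among them SAG29 (AT5G13170) at 586 ± 48.9 against 49 ± 5.5, and so were early wound and touch genes, 5 of 10 (adjusted p = 0.000717). Cell division genes were lower (median -0.66, adjusted p = 0.000373).

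Between stages 12 and 15 the organs changed to unequal extents. Carpels changed least, with 802 probe sets called (588 higher, 214 lower), and sepals, stamens and petals more, with 2973 (1225 and 1748), 4241 (2125 and 2116) and 4457 (2044 and 2413). In sepals the nuclear photosynthesis list fell, with 20 of 30 genes lower (median -1.27, adjusted p = 1.26e-12) and PORB (AT4G27440) at 42.9 ± 2.74 against 371 ± 31.3 (log2 fold change -2.82, SE 0.11, adjusted p = 2.21e-30). It rose in stamens (median 0.72, 9 genes higher and 1 lower, adjusted p = 2.07e-05), with RCA (AT2G39730) at 1780 ± 11.1 against 412 ± 14.5 (log2 fold change 2.08, SE 0.11, adjusted p = 2.57e-25), while in the same stamens 11 of 25 pollen and male gamete genes fell and 3 rose (median -0.83, adjusted p = 0.0191, and 0.0992 without a pseudocount). The photosynthesis list also rose in carpels (median 0.68, adjusted p = 2.89e-16). Senescence-associated genes rose in sepals (6 of 7), petals (4), stamens (4) and carpels (1), and SAG29 in petals was 910.3 ± 59.8 against 31.1 ± 3.31 (log2 fold change 4.44, SE 0.15, adjusted p = 3.28e-33). Neither the expansin list (adjusted p = 0.764) nor the flavonoid pathway list (adjusted p = 0.203) passed in petals, though EXPB3 (AT4G28250) of the first fell to 31.2 ± 4.83 against 453 ± 11.8 and CHIL (AT5G05270) of the second to 40.1 ± 9.88 against 877 ± 128, while CYP71B31 rose to 2564 ± 368 against 36.5 ± 3.69 (log2 fold change 5.74, SE 0.14, adjusted p = 2.08e-40). In petals the sugar exporter gene SWEET11 (AT3G48740) rose to 1067 ± 35.5 against 28.5 ± 6.19. In stamens, late embryogenesis and dehydration genes fell (7 of 11, median -2.75, adjusted p = 0.00555, and 0.103 without a pseudocount), LEA from 1192 ± 89.6 to a level below the floor, at least 52.6-fold lower. In carpels the flavonoid pathway list rose (4 genes higher and 1 lower, adjusted p = 0.00643, and 0.127 without a pseudocount), BAN of the carpel and ovule list rose to 265 ± 10.4 against a level below the floor, at least 11.7-fold higher (log2 fold change 4.24, SE 0.19, adjusted p = 3.51e-27), and DFR (AT5G42800) to 170.3 ± 5.44 against a level below the floor, at least 7.53-fold higher. The heat and chaperone list fell in carpels (median -0.52, adjusted p = 2.45e-08), with Hop3 (AT4G12400) at 54 ± 5.14 against 342 ± 36.8, and in petals (median -1.08, adjusted p = 0.0125), with ATHSP22.0 (AT4G10250) at 44.1 ± 5.49 against 618 ± 82.1. Pollen genes rose in stage 15 carpels from low levels, among them PLIM2a at 136 ± 8.89 against a level below the floor, at least 6.01-fold higher and AT59 (AT1G14420) at 77.8 ± 10.9 against a level below the floor, at least 3.42-fold higher, 5 of 25 members in all (median 0.11, adjusted p = 0.00175).

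**Figure D4:**
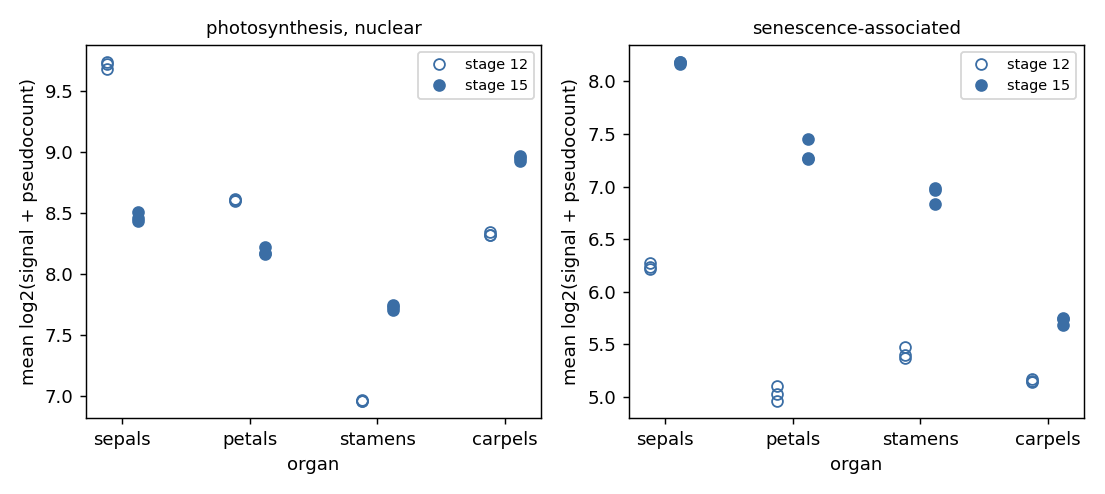
Mean log2(signal + 11.31) per array of the nuclear photosynthesis list (30 genes) and of the senescence-associated list (7 genes) in the 4 floral organs at stages 12 (open) and 15 (filled), 3 arrays each. The photosynthesis list goes down in sepals and petals and up in stamens and carpels.

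The sugar exporter genes of the SWEET family differed between organs and stages. In stage 12 stamens SWEET14 was 917 ± 29.6 against 28.8 ± 10.9 in petals and SWEET7 (AT4G10850) 544 ± 18.4 against a level below the floor in sepals, at least 24.1-fold. In stamens SWEET7 then fell to 24.7 ± 0.357 at stage 15 and SWEET3 (AT5G53190) from 492 ± 14.7 to a level below the floor, while SWEET11 rose from 179 ± 5.27 to 1788 ± 127. At stage 12 SWEET11 was highest in sepals, at 1326 ± 39.2 against 179 ± 5.27 in stamens. SWEET8 (AT5G40260), a member of the anther list, fell from 467 ± 14.5 in stage 10/11 flowers to 185 ± 31.2 at stage 12 and 22.8 ± 0.809 at stage 15. In the mutants a list of 14 SWEET genes was lower in lfy-12 (8 of 14, adjusted p = 2.87e-07) and in the other mutants except clv3-7 (adjusted p = 0.824), though in ap1-15 1 member was called higher beside 4 lower. The list is not the whole family: it leaves out, among others, AtVEX1 and SAG29, which the annotation also calls SWEET5 and SWEET15. Of the list, SWEET7 fell from 147 ± 2.17 to a level below the floor in ap3-6. Among the dissected organs of stage 12, members such as SWEET14, SWEET7 and SWEET3 were highest in stamens, and others such as SWEET1 and SWEET11 in sepals. The fall of the SWEET list in the mutants was not told apart from that of the stamen organ list.

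**Figure D5:**
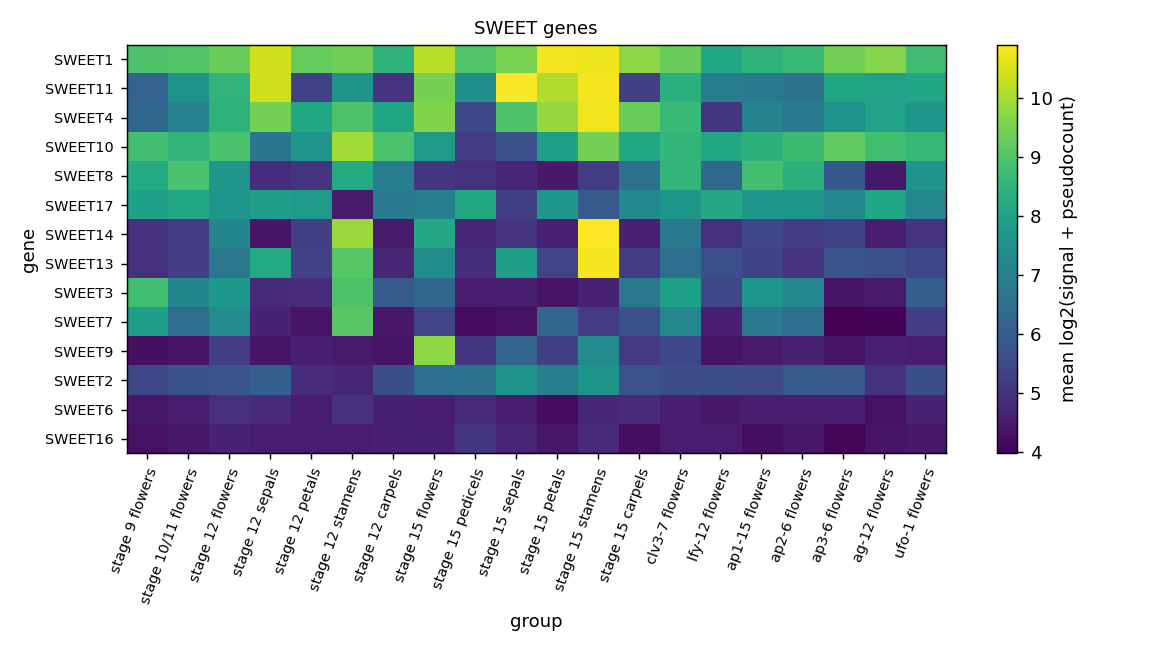
Mean log2(signal + 11.31) of 14 SWEET genes in 20 groups, 3 arrays per group, as colour. SWEET14 is brightest in stage 15 stamens (1902) and SWEET9 in stage 15 flowers (838).

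Mature pollen was compared with the stamens of open flowers, the organ it comes from. Of 8705 probe sets called, 3316 were higher in pollen and 5389 lower. This balance depends on the scaling: with quantile normalization 4379 were higher and 4611 lower, and with each array divided by its 75th percentile 6095 were higher and 3804 lower. The median log2 difference over all 17646 probe sets was -0.19, and it was 0.07 with quantile normalization and 0.40 with each array divided by its 75th percentile. List medians below are to be read against the first of these. Pollen and male gamete genes were higher, 24 of 25 (median 2.70, adjusted p = 7.21e-11), with ANX1 (AT3G04690) at 1927 ± 34.6 against 161 ± 3.03 (log2 fold change 3.49, SE 0.13, adjusted p = 7.78e-32) and AtVEX1 at 1098 ± 544 against 34.8 ± 1.13 (log2 fold change 4.48, SE 0.20, adjusted p = 2.3e-28). SEs and p-values rest on 1 spread per probe set pooled over the 22 groups, while pollen replicates correlated less than others. They can understate the spread in pollen, as for AtVEX1, whose pollen SD is large beside its mean. The cell division machinery list was higher (median 1.07, 10 of 20 members higher and 1 lower, adjusted p = 0.000801), including the Aurora kinase genes AUR1 (AT4G32830), at 2660 ± 177 against 316 ± 32.4 (log2 fold change 3.03, SE 0.08, adjusted p = 3.53e-39), and AUR2 (AT2G25880), at 2548 ± 122 against 296 ± 1.5. Meiotic recombination genes, 4 of 5 called higher, did not pass as a list (adjusted p = 0.0713, and 0.034 with only the arrays of the groups compared). FANCM (AT1G35530) among them was 171 ± 40.3 against 30.8 ± 3.93. The largest increase was of AT1G76640, 1912 ± 336 against a level below the floor, at least 83.6-fold higher (log2 fold change 7.08, SE 0.14, adjusted p = 1.43e-46). Nuclear photosynthesis genes were lower (22 of 30, median -2.83, adjusted p = 4.8e-07), RCA at 31.7 ± 9.65 against 1780 ± 11.1. The wall-loosening gene EXPA8 (AT2G40610) was below the floor against 1974 ± 29.7, at least 87.3-fold lower (log2 fold change -7.13, SE 0.07, adjusted p = 5.38e-60), COR47 (AT1G20440) 64.3 ± 14.8 against 5561 ± 345 and SWEET14 below the floor against 1902 ± 188, at least 83.8-fold lower. The ubiquitin ligase gene PUB22 (AT3G52450) was 135 ± 7.62 against a level below the floor, at least 5.97-fold higher.

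The long-day flowers have no stated stage and differ from the rest in photoperiod and temperature, so their levels were not tested. Across the 17646 probe sets, which are not independent replicates, their mean log2 profile correlated with that of stage 10/11 flowers at 0.9746 (Pearson, with Spearman 0.9723), with that of ap2-6 flowers at 0.9747 (0.9718) with that of stage 9 flowers at 0.9534 (0.9499), with that of stage 12 flowers at 0.9378 (0.9315) and with that of stage 15 flowers at 0.782 (0.7736). These 5 groups were picked for the text from 21 after the correlations were seen.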

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

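The set of 144 tests on organs and 84 tests on mutants below was chosen after the results for each organ and mutant were seen. Each test asks whether a list's log2 change differs between 2 groups under the same contrast, by the contrast of the changes themselves. Given here are those where the medians lay on opposite sides of 0, by at least 0.25 each, and the median difference was at least 0.5. The difference also had to pass with both the preset and an estimated correlation. No explanation was tested for them.

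From stage 12 to 15 the nuclear photosynthesis list changed differently in sepals (median -1.27) and petals (-0.44) than in stamens (0.72) and carpels (0.68). The median difference of changes was -2.25 for sepals against stamens (adjusted p = 6.72e-16), -1.85 for sepals against carpels (adjusted p = 4.53e-20), -1.30 for petals against stamens (adjusted p = 7.81e-10) and -1.02 for petals against carpels (adjusted p = 4.65e-07). For the mature pollen and pollen tube list it was 1.71 for sepals against stamens (adjusted p = 0.0143) and -1.33 for stamens against carpels (adjusted p = 0.00232), with medians of 0.25 in sepals, -1.09 in stamens and 0.50 in carpels. The sepal median stands at the bound of 0.25, so the place of that pair here rests on the cut-off. The late embryogenesis and dehydration list differed by 2.47 between petals and stamens (adjusted p = 6.37e-06). The flavonoid pathway list differed by -2.04 between petals and carpels (adjusted p = 0.00206, and 0.0374 with an estimated correlation), and the early wound and touch response list by 0.83 between the same organs (adjusted p = 0.025, and 0.0431).

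Among the mutants, the petal list differed between ag-12, where it was higher, and 5 mutants where it was lower. The difference was -0.68 for lfy-12 against ag-12 (adjusted p = 5.62e-62), -0.83 for ap1-15 against ag-12 (adjusted p = 5.87e-49), -0.85 for ap2-6 against ag-12 (adjusted p = 1.67e-56), -0.73 for ap3-6 against ag-12 (adjusted p = 5.29e-77) and 0.76 for ag-12 against ufo-1 (adjusted p = 1.53e-79).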

How the results depend on the processing

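All alternatives here were planned. Each of the 24 counts of called probe sets stayed within 1.5 times its value under no filter on dim probe sets, quantile normalization, division by the 75th percentile, only the arrays of the groups compared, eBayes with robust=TRUE and the replicate block, and in all 201 refits that left out 1 array. Robust eBayes and the fit to only the arrays compared leave fold changes as they are, as does the block where the letters are balanced. The 2-fold rule decides most calls: in clv3-7, 1875 probe sets passed the adjusted p alone and 123 were called. Agreement under these settings could therefore hardly come out otherwise. The replicate letters gave no sign of pairing: correlations of same-letter deviations ran from -0.139 to 0.116. Only the first letter of a label was used, so A2, B2 and C2 of stages 9 and 10/11 counted as A, B and C. A difference between these label series could therefore not be seen. It could enter the step from stage 10/11 to 12 and the choice of genes by stage 10/11 against stage 15 below. With no pseudocount the counts rose to 193 in clv3-7 (from 123), 2601 in lfy-12 (from 1729), 1506 in ap1-15 (from 984), 1814 in ap2-6 (from 1134), 972 from stage 9 to 10/11 (from 555) and 1329 for carpels from stage 12 to 15 (from 802). With a pseudocount equal to the floor the count in clv3-7 was 78. The cause was not tested. A total can hide a change of balance. With no pseudocount clv3-7 had 91 higher and 102 lower, against 75 and 48. Stamens from stage 12 to 15, at 2125 higher and 2116 lower, had 1736 and 1759 with a pseudocount equal to the floor and 2134 and 2142 without stage 12 replicate B. In pollen the share of lower calls went from 61.9% to 51.3% with quantile normalization and 38.4% with the 75th percentile.

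The petal list in clv3-7 had a median of -0.063 with no pseudocount and no longer passed (adjusted p = 0.0753). The carpel list in ag-12 passed as lower with a pseudocount equal to the floor (median 0.007, adjusted p = 0.009), quantile normalization (0.035, adjusted p = 0.0267) and the 75th percentile (-0.014, adjusted p = 0.0339), so its call rests on the setting, and its median changed sign under the last. The cause was not tested.

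Of the 103 gene comparisons in the report, 101 kept direction and call with no pseudocount and all 103 under the other alternatives, including 753 refits without 1 array. The exceptions were AMS in ap1-15 and from stage 9 to 10/11. Of the 69 list tests in the report, 65 kept their side with no pseudocount. The anther and tapetum list in ap2-6, the late embryogenesis and dehydration list and the pollen and male gamete list in stamens and the flavonoid pathway list in carpels did not. With only the arrays of the groups compared 68 kept it, the exception being meiotic recombination in pollen. With an estimated correlation 61 did, the 8 exceptions all being chloroplast-encoded. All 69 kept it under the other alternatives.

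The correlations of long-day flowers with stage 9, 10/11, 12, 15 and ap2-6 flowers moved by more than the spread between replicates. With no pseudocount they were 0.9326, 0.9619, 0.9169, 0.7334 and 0.9665, with a pseudocount equal to the floor 0.9571, 0.9758, 0.9415, 0.7911 and 0.9756, without the filter 0.9688, 0.983, 0.9606, 0.8644 and 0.9829, and with quantile normalization 0.9554, 0.9752, 0.9399, 0.7875 and 0.9753. The cause was not tested. Signal over background limits what can be said of genes below the floor.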

Other observations

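Of the tests below, the 2 on fewer stamens, those on younger ap1-15 and ap2-6 flowers, the 2 on green tissue, that on scaling as the whole cause, that on regroupings that mix organs and that on deviations from the group means were chosen only after the result was seen. The others were written before. No biological explanation was tested beyond these, and all patterns were found in the same data.

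The anther and tapetum list was higher in clv3-7, ap1-15 and ap2-6 flowers than in stage 12 flowers. A test of fewer stamens on the list itself, whose lowest median in the 3 was 0.396, decides nothing, because these mutants were picked for that list. By the bound as first written it counted against fewer stamens, and the verdict was changed to undecided after that was seen. In clv3-7 the stamen organ list, without the genes of the 2 anther lists, was not lower (median 0.067, 14 of 1687 members higher and 0 lower). The median over all genes tested was 0.016. This gives no sign of fewer stamens in clv3-7. A shift under 0.1 does not exclude a small loss. In ap1-15 and ap2-6 the whole stamen organ list was lower (medians -0.429 and -0.57), and fewer stamens stay open there. Fewer stamens would lower the anther list, so they do not account for its higher level. A candidate explanation for the higher anther list is that these flowers were younger than stage 12. It was tested on 559 genes, outside the stage 12 organ lists and the 2 anther lists, higher in stage 10/11 than in stage 15 flowers, and on 872 lower there. The test written before asked for a median of the early genes above 0.1 in each of the 3 mutants and of the late genes below -0.1. In clv3-7 the early genes had a median of 0.083, short of the bound, and the late genes one of -0.009. By the bound as first written this counted against the explanation. After that was seen the verdict was changed to undecided, on the ground that the quartiles of the early genes (-0.076 to 0.324) straddle the bound. Quartiles give the spread between genes, not the error of the median, so this ground does not hold. For clv3-7 the verdict as first written stands. For ap1-15 and ap2-6 alone, separated after the clv3-7 result, the lower early median was 0.429 and the late medians -0.148 and -0.279. These pass the bounds, as younger flowers would. Cell division genes and genes enriched in organs only at stage 15 were not left out of the early and late genes. A change of organ make-up could move these as well, so the test cannot tell it apart from age. The cell division machinery list was higher in lfy-12, ap1-15, ap2-6 and ap3-6. The wild-type step from stage 10/11 to 12 moved the early and late genes by -0.523 and 0.33. The bounds were also passed in lfy-12 (0.435 and -0.298), where the anther list did not pass, and in ap3-6 (0.181 and -0.113), where it was lower. In ag-12 (0.23 and -0.064) and ufo-1 (0.185 and 0.002) the late genes fell short. Differences between mutants were not tested. In lfy-12 and ap3-6 the stamen organ list was lower (medians -1.01 and -0.981), so an anther list that is not higher there decides nothing about age. A change of genotype that itself delays anthers stays open.

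Chloroplast-encoded genes were higher in 6 mutants than in stage 12 flowers with the preset correlation, a call lost in all 6 with an estimated correlation (adjusted p from 0.143 to 0.371), and 10 to 22 of the 69 genes were called. In clv3-7 the list's median was 0.168, with 4 genes called. Variation between arrays unrelated to genotype might give this. The pooled SD between replicates of the list's mean log2 signal was 0.135, between the bounds of 0.1 and 0.25 set beforehand, and decides nothing. The lowest of the 18 mutant arrays stood at 9.124 and the highest stage 12 array at 8.75, but a shift shared by the 3 stage 12 arrays stays open. More green tissue in the mutants predicts a higher nuclear photosynthesis list, whose highest median was 0.128 and which was negative in 3 mutants, again between the bounds. That green tissue raised both kinds of gene together is argued against by the distance from the nuclear list's 75th percentile up to the chloroplast-encoded median, at least 0.475 in each of the 6. This second test was added after the first was undecided. A change confined to plastids stays open and untested. So do fewer stamens and younger flowers. Among stage 12 organs the chloroplast-encoded list's mean log2 signal was lowest in stamens (7.87, against 8.809 to 9.571 in the others). In these 6 mutants the stamen organ list was lower. The nuclear photosynthesis list was also lowest in stage 12 stamens but did not rise likewise. Stage 9 and 10/11 flowers stood at 9.357 and 9.555, the 6 mutants at 9.176 to 9.521 and stage 12 flowers at 8.654.

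The cell division machinery list was higher in pollen than in stage 15 stamens. Scaling of all arrays to the same trimmed mean may raise dim transcripts in pollen. The 5100 probe sets removed as dim had a median difference of 0.274 (quartiles 0.054 and 0.565), short of what the explanation needs and beyond what would exclude it. Scaling as the whole cause is argued against by quantile normalization and the 75th percentile, which moved the median over all genes from -0.189 to 0.074 and 0.4. Net of that median the list stood at 1.255 as deposited and at 1.554 and 1.382, and at 1.022 or more in each of the 9 pairs of a pollen and a stamen array under both. That scaling adds a part stays open, because all 3 settings bring the arrays to a common level. The test of a larger share of the signal in the brightest probe sets of pollen as the cause decides nothing. It asked for a fall of the list's median to 0.5 or less under the 2 rescalings. The median was 1.627 or more, against 1.065 as deposited. Both rescalings raised the median over all genes, so such a fall could hardly come out. No biological explanation was tested for this pattern.

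For the 15 comparisons of 2 groups, 6 arrays make 10 splits, too few for a share under 0.05. In each, 1 of the 10 splits, the real one, gave as many calls. The real counts were 123 to 4457 with at most 3 in any other split, and 8705 for pollen against stage 15 stamens, with 1122 in the highest other split.

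For enriched probe sets 100 regroupings of the arrays were counted, the real one included. By the bound set beforehand chance counted as excluded for stage 12 stamens (4 regroupings as large, real 1691, highest other 1970), stage 12 carpels (3, real 894, highest other 1985), stage 15 carpels (1, real 2558, highest other 1109) and stage 15 pedicels (1, real 442, highest other 433). It was not excluded for stage 12 sepals (6, real 1199, highest other 2187), stage 12 petals (7, real 294, highest other 1969), stage 15 sepals (6, real 920, highest other 2967), stage 15 petals (6, real 227, highest other 1104) and stage 15 stamens (5, real 863, highest other 1214). The regroupings with larger counts point to a structure of the samples: of those as large as the real one, all 5 for stage 12 sepals, all 3 for stage 12 stamens, both for stage 12 carpels, all 5 for stage 15 sepals and all 4 for stage 15 stamens kept the 3 arrays of a single organ together. For petals this held for 1 of 6 at stage 12 and 1 of 5 at stage 15. Such regroupings carry the differences between organs, so this count shows no difference in evidence between stage 12 sepals and stamens. For each of these 2 organs 5 such regroupings were drawn, of which 5 and 3 called as many. A further count left them out, with 95 to 100 regroupings per organ, the real one included. In it 1 regrouping was as large, the real one, for stage 12 sepals (highest other 723), stamens (489) and carpels (398) and stage 15 sepals (335), stamens (440), carpels (352) and pedicels (433). For petals 6 were as large at stage 12 (highest other 715) and 5 at stage 15 (424). Regroupings that mix organs still carry differences between them and put unlike arrays in 1 group. They are no model of chance, so this count excludes it for no organ. In a last count the differences between organs were removed and the deviations of the arrays from their group means, brought to their full variance, were regrouped. For each of the 9 results, petals included, the highest count among these regroupings was 0. The real count they were set against was taken with the differences between organs in place. So this shows only that deviations of this size make no calls under the 2-fold rule. It decides nothing more about the groupings.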
